A study of Rattus norvegicus with 15 samples.

How the data were processed

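Gene expression was measured with one-colour arrays, on total RNA of the mandibular incisor enamel organ labelled with Cy3. Per the labels' protocols, RNA was prepared with a miRNeasy kit and amplified and labelled with a one-colour kit for low RNA input. Per the submitters' processing notes, images were read with Agilent Feature Extraction 11.0.1.1. Per the file headers, each scanner file holds spot intensities on a linear scale, with a processed signal from which background had been subtracted, the median signal, the local background and flags for spots well above background, saturated or uneven. The authors' deposited series table holds log2 values of 38237 probes. These covered 28800 of the 28863 features tested and none of the RefSeq genes, whose results could therefore not be checked against the table. Set against the scanner values of each array, its columns had slopes of 0.949 to 1.06 over the brighter probes and correlations of 0.986 to 0.995 with the log2 processed signal, medians of 5.72 each and the same maximum of 18.1. These values show a log2 scale, the same direction and no centring of genes. How the authors normalized the table is not given in the sources used here. Equal medians and maxima are what quantile normalization leaves. Between secretory stage and cervical loop the table's values gave 7523 features higher and 8960 lower, against 7591 and 8927 with quantile normalization. The series table is therefore not a separate check beside quantile normalization.

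Stages were taken from the tissue characteristic, which the description and source name follow, and replicate numbers from the sample titles. The titles of 8 arrays name the other of the secretory and maturation stages, and the analysis with stages from the titles was kept as an alternative. Scans were numbered from the file headers. Scan 1 held maturation replicates 1 to 4, scan 2 maturation replicate 5 with secretory replicates 1 to 3, scan 3 secretory replicates 4 and 5, scan 4 cervical loop replicate 5 and scan 5 the other cervical loop arrays. Scans 1 to 3 were made on scan day 1, and scans 4 and 5 on scan day 2.

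The spots of a probe were averaged on the linear scale, and the log2 of that processed signal minus the array's 75th percentile was used. Control spots and spots flagged as uneven or as outliers were left out, between 107 and 276 spots per array; saturated spots would have been kept, and there were none. A probe counted as well above background on an array where at least 50% of its spots were. The 28863 features tested were well above background on all 5 arrays of at least 1 stage, with the probe of highest mean signal standing for a gene with several. These were 37 RefSeq genes, 390 ultraconserved-element probes, 28410 probes with an array maker's identifier, 20 with an accession that matched no gene and 6 custom probes. Accessions were matched without versions to the transcripts of a RefSeq gene table of the assembly GRCr8, which was used for names only; 39 of 62 matched and 23 did not. Lhcgr, the only RefSeq gene not tested, was well above background on 0 arrays.

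The stages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in one fit over the 15 arrays without a block. P-values were adjusted by Benjamini-Hochberg over all features of a comparison, with a threshold of 0.05. A fold minimum of 2 was applied to the measured differences where stated. Features highest in a stage passed both criteria against both other stages. Folds are given as lower bounds (at least) where a probe was well above background on no array of a stage. The same was done for 1 or 2 arrays, a case added after the data were seen. The brighter stage's mean was set against, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Means were of normalized log2 values. That lowest signal is a lenient limit, and the bounds hold for the processed signal only. With normexp correction differences could be smaller or of opposite sign. Shifts of the ultraconserved-element probes were tested with camera, with its preset correlation of 0.01 and with an estimated one of 0.158, and adjusted over the 3 comparisons. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plotted with matplotlib 3.10.9.

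The groups, tests, filters, alternatives and the rule for naming genes were chosen before the data were examined. Per comparison the rule takes the 6 named genes with the largest increase and the 6 with the largest decrease, and 4 non-coding transcripts in each direction. They had to pass the threshold, not overlap between the stages, and be well above background on all 5 arrays of the higher stage. No accession marked a transcript as non-coding, so the ultraconserved-element probes took that place, a choice made after the array contents were seen; probes without a name were also added then. The 21 gene lists fixed in advance, for enamel matrix, ion transport, cell cycle, other cell types and the like, could not be tested, since none reached the minimum of 5 genes named on the array; 2 of them had 1 gene each, Gusb and Sdha, and the others none. The enamel genes of the rule were not among the named probes either.

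The test was checked on simulated data over 28471 probes with the spread of these arrays. For maturation against secretory stage it recovered 7.46% of probes changed by 0.5 on the log2 scale, 70.2% of those changed by 1 and 97.0% of those changed by 2, and called 0.0389% of unchanged probes. The simulation changed only 67, 67 and 66 probes by these amounts, with independent noise. Far more features were called in the real comparison, so these rates do not carry over to its counts.

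Replicate numbers were checked as pairs, since the stages came from the same 5 rats per the series design while no label ties a number to a rat. Deviations from the stage means of same-numbered maturation and secretory arrays correlated at 0.28, 0.289, 0.225, 0.107 and 0.263, each over 0.1, which by the rule set beforehand marks them as pairs; the fit reported here keeps the planned design without a block, and the pairs enter as an alternative and in splits of the arrays. Because no label says how rats and samples correspond, p-values of the fit without a block measure the spread between these samples.

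The alternatives were quantile and median scaling, normexp background correction, other filters on dim probes, the series table's values, the replicate number or the scan as a block, fits of 2 stages, eBayes with trend and robust, array weights, every probe on its own, stages from the titles, and leaving out each array. The normexp correction (offset 50) planned on the mean signal was run on the median signal instead, a choice made after the data were seen; the mean signal was not used here.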

Results

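Long non-coding RNA array profiles were analysed from the enamel organ of the rat mandibular incisor, a tooth that grows throughout life and therefore carries all stages of enamel formation along its length. The enamel organ is the epithelium that makes enamel. Its cervical loop is the growing end, where the progenitors of the enamel-forming ameloblasts lie. In the secretory stage ameloblasts lay down the enamel protein matrix, and in the maturation stage the matrix is removed and mineral is added. Tissue of these 3 stages came from 4-week-old Wistar Hannover rats, with 5 samples per stage and 5 rats per the series design, and each of the 15 RNA samples was hybridized to its own array. Each array held 41623 spots of 38321 probes apart from control spots. Of these probes, 37277 carried only an identifier of the array maker and 962 stood for both strands of 481 ultraconserved elements, short stretches of DNA that are identical in human, mouse and rat. A further 62 probes carried a transcript accession, of which 39 were matched to 38 named RefSeq genes. The text therefore names the RefSeq genes and the ultraconserved elements, with the element's number and the strand as the array files give them. Between 67.4% and 78.9% of the spots of an array were well above background, and the number of arrays limits the precision of each value.

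Stages were taken from the tissue label. The sample titles exchanged secretory and maturation for replicates 2 to 5 of both stages, so that title and tissue label disagreed for 8 of the 15 arrays. The arrays fell into 3 groups that followed the tissue label; which of the 2 groups is secretory and which maturation, and with it each direction between them, rests on the labels and not on marker genes. Correlations across probes were 0.985 to 0.992 among secretory arrays and 0.989 to 0.995 among maturation arrays, against 0.930 to 0.951 between these stages. Cervical loop arrays correlated with each other at 0.974 to 0.987. Of the 28863 features tested, 23945 differed among the stages (limma F test, adjusted p under 0.05).

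**Figure D1:**
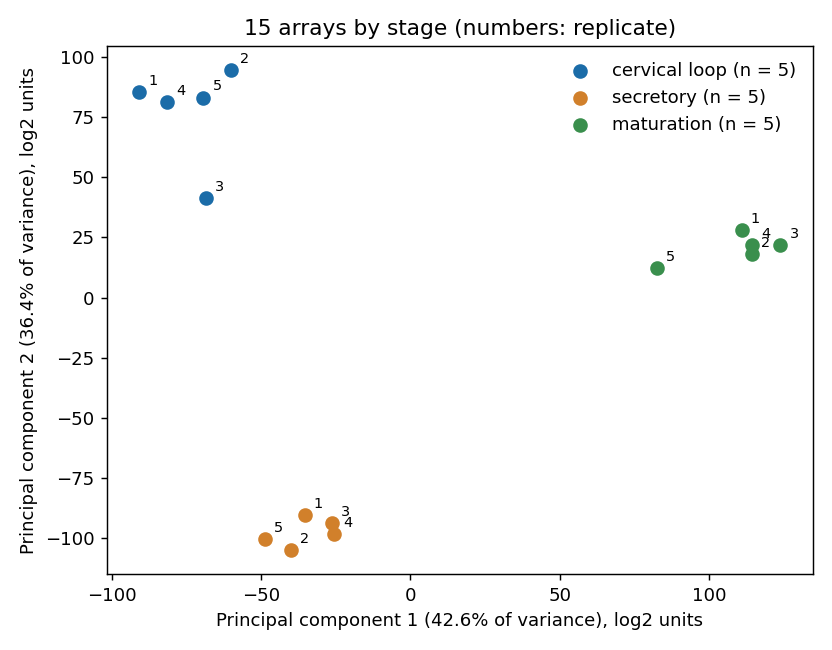
Principal components 1 (horizontal, 42.6% of the variance) and 2 (vertical, 36.4%) of the normalized log2 signals of the 15 arrays; each point is 1 array, coloured by the stage of its tissue label and numbered by replicate. The 5 maturation arrays lie at 82.7 to 124 on component 1, and cervical loop replicate 3 lies at 41.2 on component 2 against 81.4 to 94.6 for the other cervical loop arrays.

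The first comparison asked how transcript levels of the tissue differ between the cervical loop and the secretory stage. No gene of the lists for other cell types was named on the array. In all comparisons a change in the mix of cells therefore cannot be told apart from a change within the epithelium. Among the named genes, Cdh2, which encodes N-cadherin, rose most, from a normalized log2 signal of 1.19 ± 0.41 in the cervical loop to 3.20 ± 0.36 in the secretory stage (SD, n = 5 each; difference 2.01, SE 0.19, adjusted p = 5.27e-07). Pld1, which encodes phospholipase D1, rose by 1.61 on the log2 scale (adjusted p = 4.98e-06). Ndfip1 and Ndfip2, which encode adaptors of Nedd4-family ubiquitin ligases, rose by 1.25 (adjusted p = 1.04e-06) and 1.01 (adjusted p = 2.14e-05). Map2, which encodes a microtubule-associated protein known from dendrites, was measured on all 5 cervical loop arrays and on none of the secretory arrays, and was at least 3.63-fold lower there (adjusted p = 6.72e-06); with normexp background correction its difference was -0.24 and did not pass the threshold. Fgf2, a fibroblast growth factor, fell by 1.76 (SE 0.16, adjusted p = 2.65e-07; difference -0.40 with normexp correction).

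Of the 37 RefSeq genes tested, 9 rose from cervical loop to secretory stage, 19 fell and 9 did not pass the threshold. Besides Map2 and Fgf2, the rule for naming genes took Cyp2e1, Actb, Dlg4 and Med16 as the largest decreases. Actb, which encodes beta-actin, fell by 1.19, Dlg4, which encodes the scaffold protein PSD-95, fell by 1.14 (difference -0.27 with normexp correction), and Med16, a Mediator subunit, fell by 1.11. Cyp2e1, a cytochrome P450 gene, was not well above background on any secretory array and was at least 1.66-fold lower, so that its rank among the decreases was not measured. Its call did not hold under quantile normalization (difference -0.70), and with normexp correction its difference was 0.14, of opposite sign and short of the threshold.

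Ultraconserved-element probes changed in both directions between these stages. Of 390 tested, 84 were higher and 159 lower in the secretory stage, 36 and 65 of them at least 2-fold. This majority turned with the processing: 129 were higher and 99 lower with quantile normalization, 117 and 109 with median scaling, 132 and 92 with the series table's values, and 142 and 27 with normexp correction (15 and 2 at least 2-fold). Of the 101 at 2-fold, 28 were not well above background on any array of the dimmer stage, and 19 of these had a lower bound under 2-fold. The probe uc.125- was at least 44.9-fold higher (adjusted p = 2.02e-08) and was well above background on 2 of the 5 cervical loop arrays; its difference was 2.95 with normexp correction. The probes uc.277+, uc.428+ and uc.398- rose by 4.71, 3.90 and 3.85 (SE 0.57, 0.61 and 0.33); uc.277+ and uc.428+ varied among cervical loop arrays, with SDs of 1.69 and 1.85 (n = 5). In the other direction, uc.195- was at least 10.1-fold lower, uc.220- at least 4.78-fold, uc.247+ at least 4.44-fold and uc.337+ at least 3.61-fold, each measured on all 5 cervical loop arrays and on none of the secretory arrays. With normexp correction uc.195- and uc.220- differed by -0.83 and -0.37, and uc.247+ and uc.337+, at -0.37 and -0.31, did not pass the threshold; with the series table's values uc.337+ differed by -2.21. A shift of the whole group against other probes did not pass the threshold (camera, adjusted p = 0.851), while their median of -0.23 lay above that of random sets of unnamed probes of the same signal levels (-0.46 to -0.27 in 95% of 10000 sets).

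In total, 16769 features differed between secretory stage and cervical loop, 6172 higher and 10597 lower in the secretory stage, and 6996 differed at least 2-fold (2556 higher, 4440 lower). Among probes without a gene name, ASRNV20023150 rose by 8.67 and ASRNV20022343, not well above background on any secretory array, was at least 179-fold lower. The share of higher calls was 36.8%, and it was 53.8% with median scaling and 56.9% with normexp background correction, under which 2902 features differed at least 2-fold. Median scaling moved the median difference of all features from -0.19 to 0.03, and all cervical loop arrays were scanned on another day than the other arrays, so that stage and scan day cannot be told apart.

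**Figure D2:**
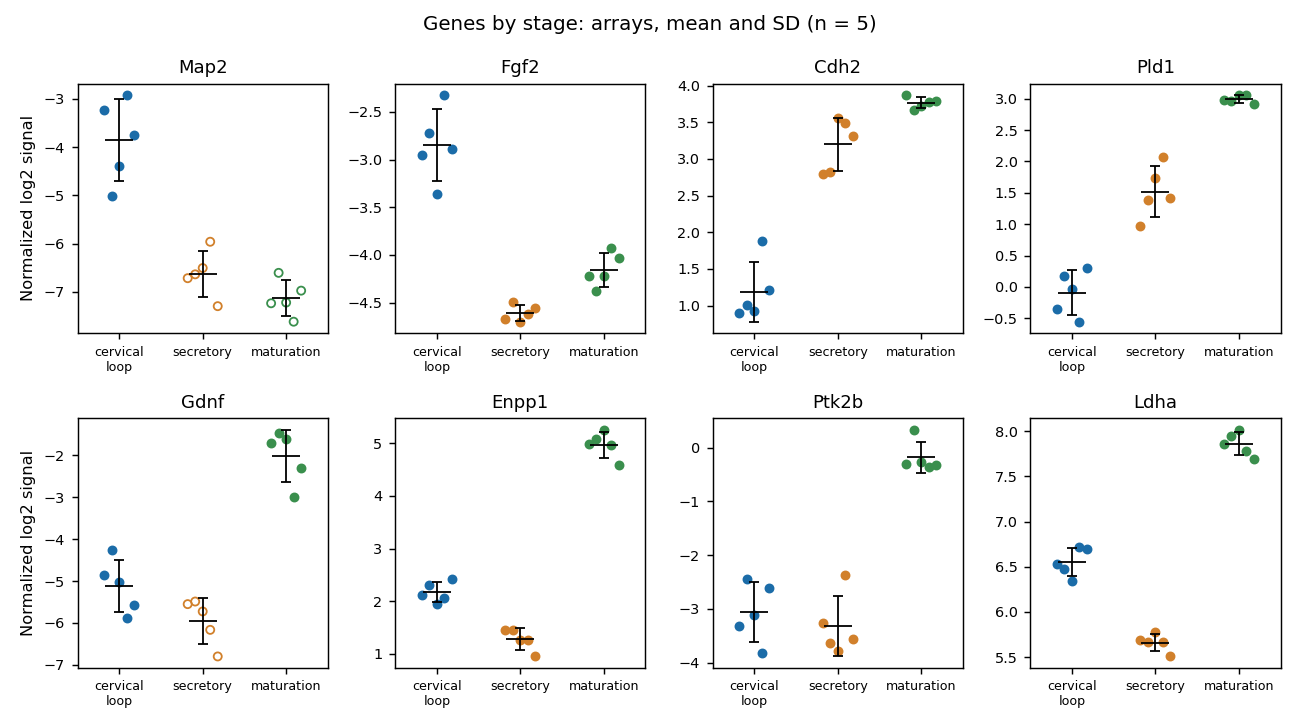
Normalized log2 signals (vertical, log2 relative to the array's 75th percentile) of 8 genes in the 3 stages (horizontal); points are arrays, open where fewer than 5 arrays of the stage were well above background, and bars give mean and SD, n = 5. Enpp1 lies at 4.97 ± 0.25 in maturation against 1.27 ± 0.21 in the secretory stage; vertical axes differ between panels.

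The second comparison asked how transcripts change from the secretory to the maturation stage. Gdnf, which encodes a neurotrophic growth factor, was at least 11.6-fold higher in maturation (adjusted p = 1.4e-07) and was well above background on 2 of the 5 secretory arrays; its difference was 1.09 with normexp correction. Enpp1, which encodes an enzyme that makes pyrophosphate, an inhibitor of mineral deposition, rose from 1.27 ± 0.21 to 4.97 ± 0.25 (SD, n = 5 each; difference 3.70, SE 0.15, adjusted p = 5.42e-11). Ptk2b, a non-receptor tyrosine kinase gene, rose by 3.14 (1.96 with normexp correction), and Hprt1, which encodes an enzyme of purine salvage, rose by 2.21. The glycolytic genes Ldha and Pgk1 rose by 2.20 (SE 0.11, adjusted p = 4.3e-10) and 1.57; a second Ldha probe rose by 2.52.

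Increases prevailed among the named genes, which are the few that the array allows to be named and need not stand for other genes. Of the 37 RefSeq genes, 24 rose, 2 fell and 11 did not pass the threshold; 19 rose and 2 fell with quantile normalization, and 28 rose and 1 fell with median scaling. Of the 2 that fell, Cyp2e1 was well above background on 1 maturation array and on 0 secretory arrays, so that its fall was not measured, and it lost its call under both scalings; Eif4b passed with quantile normalization only. Rplp1, which encodes a ribosomal stalk protein, fell from 8.22 ± 0.04 to 7.57 ± 0.18 (SD, n = 5 each; difference -0.66, adjusted p = 0.000256; -0.35 with quantile normalization and -0.44 with median scaling).

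Ultraconserved-element probes went mostly the other way, though they were not compared with the named genes at matched signal levels. Of 390 tested, 206 were lower and 31 higher in maturation, 67 and 12 of them at least 2-fold (32 and 14 with quantile normalization, 36 and 15 with median scaling, 30 and 12 with the series table's values, 15 and 2 with normexp correction). Of the 79 at 2-fold, 17 were not well above background on any array of the dimmer stage, and 10 of these had a lower bound under 2-fold. The median difference was -0.53 against -0.12 for all features. As a group they were lower than other probes with camera's preset correlation (adjusted p = 6.06e-05), and this call held neither with the correlation estimated from the data (adjusted p = 0.476) nor with the scan as a block (adjusted p = 0.0614). Of the probes that had risen in the secretory stage, uc.125- was at least 69.3-fold lower (adjusted p = 1.25e-09; measured on 1 of 5 maturation arrays), uc.398- fell by 4.65 and uc.277+ fell by 4.54; with normexp correction uc.125- and uc.398- differed by -3.09 and -3.05. The probe uc.199- was at least 5.89-fold lower and not well above background on any maturation array; its difference was -0.88 with normexp correction and -2.57 with the series table's values. In the other direction, uc.454- was at least 8.83-fold higher, uc.217+ at least 2.77-fold and uc.129- at least 1.46-fold, none of them well above background on a secretory array. The probe uc.6- rose by 1.97. With normexp correction the difference of uc.454- was 0.84, that of uc.129- was -0.12, of opposite sign, and that of uc.217+ was 0.08, neither past the threshold.

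**Figure D3:**
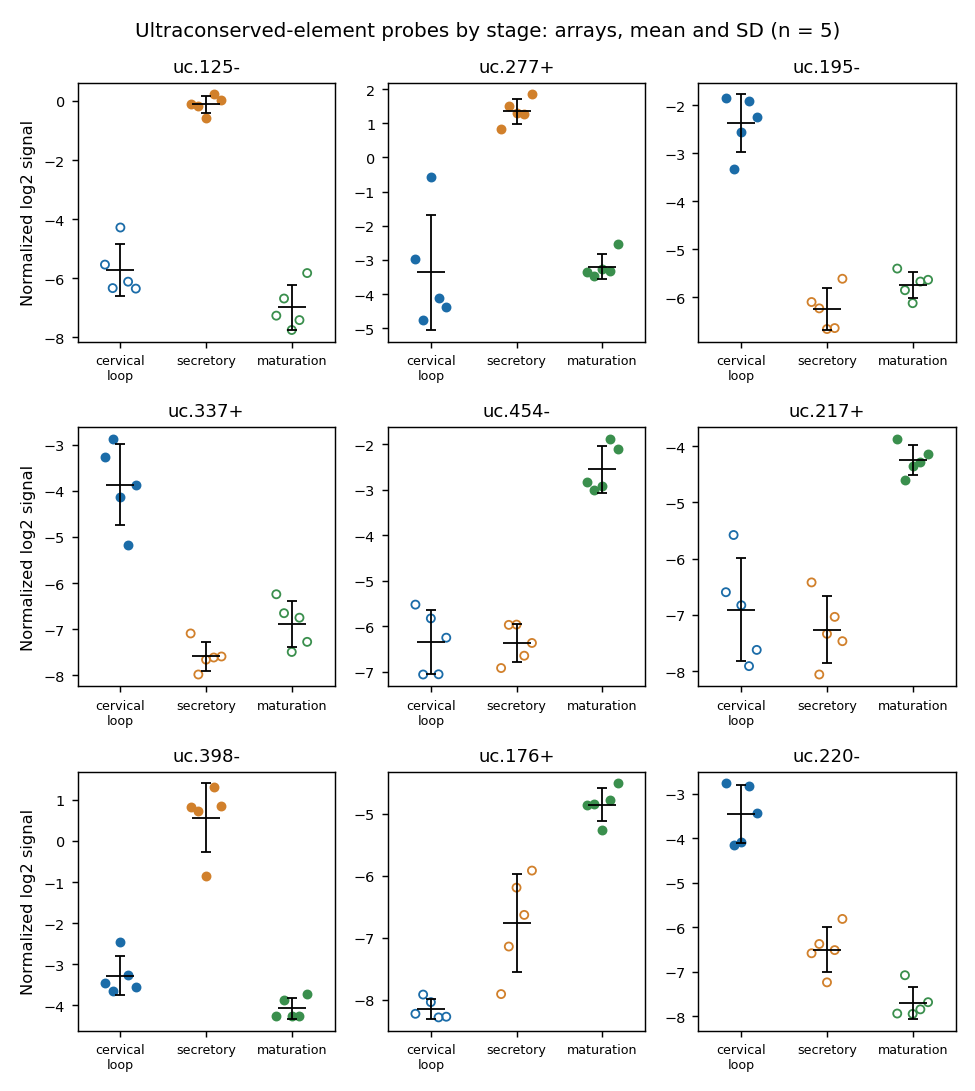
Normalized log2 signals (vertical, log2 relative to the array's 75th percentile) of 9 ultraconserved-element probes in the 3 stages (horizontal); points are arrays, open where fewer than 5 arrays of the stage were well above background, and bars give mean and SD, n = 5. The probe uc.125- lies at -0.12 ± 0.30 in the secretory stage against -5.73 ± 0.87 in the cervical loop and -7.00 ± 0.76 in maturation; vertical axes differ between panels.

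In total, 17160 features differed between maturation and secretory stage, 7245 higher and 9915 lower in maturation, and 6491 differed at least 2-fold (2924 higher, 3567 lower). The unnamed probe ASRNV20023150 fell by 10.94 and was measured on 4 of 5 maturation arrays. The share of higher calls was 42.2%, with 57.8% under median scaling and 30.8% under normexp correction, which left 3057 features at least 2-fold apart. One scan held both stages, maturation replicate 5 with secretory replicates 1 to 3: 5035 features differed with the scan as a block, 3393 within these 4 arrays alone, where the lone maturation array is assumed to vary like the 3 secretory arrays. Enpp1 and Ptk2b differed there by 3.20 and 3.24, while uc.6-, at 1.18, no longer passed the threshold with the block.

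The third comparison set both ends of the sequence side by side. From cervical loop to maturation, Gdnf rose by 3.10 (SE 0.34, adjusted p = 1.6e-06; 1.29 with normexp correction), Pld1 by 3.09, Ptk2b by 2.88, Enpp1 by 2.81, Cdh2 by 2.58 and Hprt1 by 1.97. Pld1 went from -0.09 ± 0.36 in the cervical loop to 3.00 ± 0.06 in maturation (SD, n = 5 each; adjusted p = 4.81e-09). Map2 was not well above background on any maturation array and was at least 5.69-fold lower than in the cervical loop (adjusted p = 9.32e-07; difference -0.60 with normexp correction). Cyp2e1 was at least 2.60-fold lower and was measured on 1 of 5 maturation arrays; its difference was -1.14 with quantile normalization, and with normexp correction it was -0.27 and did not pass the threshold. Fgf2 fell by 1.31 and Dlg4 fell by 1.06; with quantile normalization, median scaling and normexp correction the differences were -0.81, -0.87 and -0.53 for Fgf2 and -0.60, -0.62 and -0.47 for Dlg4. Actb fell by 0.88 (difference -0.44 with median scaling). Eif4b, which encodes a translation initiation factor, fell by 0.65, a call that did not hold with median scaling (difference -0.21).

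Of the 37 RefSeq genes, 17 rose, 10 fell and 10 did not pass the threshold; with median scaling 21 rose and 5 fell. Ultraconserved-element probes were mostly lower in maturation: 232 of 390 were lower and 39 higher, 129 and 17 of them at least 2-fold (51 and 33 with quantile normalization, 39 and 30 with the series table's values, 8 and 6 with normexp correction). Their median difference was -0.65 against -0.28 for all features; 4.35% of 10000 random sets of unnamed probes of the same signal levels had a median as low (95% of them from -0.66 to -0.45; camera, adjusted p = 0.000296, and 0.476 with an estimated correlation, which ends the call). The probe uc.220- was at least 7.79-fold lower and uc.350+ at least 3.54-fold lower, both without a maturation array well above background. The probe uc.195- fell by 3.36 and was measured on 4 of 5 maturation arrays, and uc.378- fell by 3.21. The probe uc.454- was at least 10.5-fold higher (adjusted p = 9.47e-08; measured on 2 of 5 cervical loop arrays), and uc.217+, uc.287+ and uc.176+ were at least 3.76-fold, 2.76-fold and 2.52-fold higher. With normexp correction uc.220-, uc.350+, uc.195- and uc.378- differed by -0.79, -0.37, -1.12 and -1.33, and uc.454-, uc.217+, uc.287+ and uc.176+ by 1.18, 0.39, 0.40 and 0.40. With the series table's values uc.220- and uc.350+ differed by -2.58 and -1.41, and uc.287+ and uc.176+ by 1.98 and 1.97.

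In this comparison 18255 features differed, 5936 higher and 12319 lower in maturation, and 8193 differed at least 2-fold (2385 higher, 5808 lower). The unnamed probe ASRNV20014000 rose by 12.40, and ASRNV20022343 was at least 291-fold lower. The share of higher calls was 32.5%, with 45.7% under quantile normalization and 61.8% under median scaling, and 2840 features were at least 2-fold apart with normexp correction. Stage and scan day cannot be told apart here either.

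Transcripts that stood at least 2-fold above both other stages by their measured signals were counted for each stage. There were 2713 such features in the cervical loop, among them Map2, Fgf2, Dlg4 and 51 ultraconserved-element probes. Fgf2 and Dlg4 did not reach 2-fold against maturation with quantile normalization or median scaling, and none of the 3 genes reached it with normexp correction. The secretory stage had 1505, with 18 ultraconserved-element probes and no RefSeq gene. Maturation had 1344, among them Pgk1, Ptk2b, Ldha, Gdnf, Hprt1, Enpp1, Pld1 and 7 ultraconserved-element probes. With lower bounds in place of folds to stages without an array well above background, 2394, 1505 and 1301 features remained, with 35, 18 and 6 ultraconserved-element probes. Both comparisons behind each count share the arrays of that stage. Independent lists would share 893, 316 and 242 features, and data simulated with no stage difference gave 0 in each stage. Neither shows what shared arrays add where stages do differ. With the stage's arrays split so that no array was shared, the median counts were 2524, 1433 and 1279 over 20 splits each. Which stage led depended on the processing: the cervical loop had 1619 and maturation 2340 with median scaling, 1569 and 1593 with the series table's values, and with normexp correction the cervical loop had 630, the secretory stage 975 and maturation 835.

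More ultraconserved-element probes were detected in the cervical loop, where 46.8% ± 4.7 were well above background, than in the secretory stage (37.0% ± 2.3) or in maturation (38.3% ± 4.3; SD, n = 5 arrays each). Exact two-sided permutation tests gave p = 0.0159 against the secretory stage and p = 0.0317 against maturation, both 0.0476 after adjustment over 6 tests. The share of probes with an array maker's identifier that was detected differed too, at 79.8% ± 2.5, 72.8% ± 2.0 and 74.8% ± 3.2 in the same order. On all 5 arrays of a stage and on no other array, 250 probes were well above background for the cervical loop, 48 for maturation and 9 for the secretory stage. They included 15 ultraconserved-element probes of the cervical loop, uc.217+ and uc.176+ of maturation and uc.392- of the secretory stage. All cervical loop arrays were scanned on another day than the others. For each contrast of this paragraph with the cervical loop, stage and scan day therefore cannot be told apart.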

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

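The tests of a wrong stage label for cervical loop replicate 3 and of exchanged stage names, and the reading of the other tests of that replicate as undecided, were chosen only after the result was seen. In each stage of 5 arrays, a value was singled out where its gap to the nearest other array was over 0.71 of the stage's range. Chance alone singles out about 1 in 20 stages, or 6.15 of the 123 tested, and 10 were found.

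Cervical loop replicate 3 lay at 41.2 on principal component 2, against 81.4 to 94.6 for the other cervical loop arrays. This is toward both other stages, with maturation arrays at 12.3 to 28.1 and secretory arrays at -105 to -90.3. Its mean correlation with the secretory arrays was 0.956, against 0.924 to 0.934 for the other cervical loop arrays. With the maturation arrays it was 0.946, against 0.932 to 0.940. Its correlations with the other cervical loop arrays, 0.977 or more, all lay above those with the secretory arrays, 0.964 or less (means 0.0243 apart), which argues against a wrong stage label. Genes highest in the secretory stage, chosen without this array, lay above their level in the other cervical loop arrays by 0.43 (log2) more than genes highest in maturation of similar level, and by 0.40 over genes well above background on the other 4 arrays. The secretory genes themselves lay at 0.41 and 0.37, and the maturation genes at -0.02 and -0.03. A lift common to both sets was thus not seen in this array. Bounds set beforehand, the highest values of the other arrays (0.12 and 0.14), would have read this as secretory-stage tissue in the sample and not as a brighter array, but they left out the lower side, where replicate 2 lay at -0.49 and -0.47, as far off. Both excesses also restate in part the position on the component, so that secretory-stage tissue, a brighter array and tissue taken at another position along the tooth cannot be told apart.

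Sample titles and tissue labels disagreed for 8 secretory and maturation arrays. With stages from the titles, limma called 0 features between maturation and secretory stage (7184 at an unadjusted p under 0.05), against 17160 with the tissue labels, a ratio of 0. This argues against titles that are right for all arrays. An exchange of the 2 stage names for all arrays would leave the groups and the count as they are and turn each direction between these stages; 0 genes of the enamel matrix and maturation lists fixed beforehand were named on the array, so that this cannot be told apart from right labels.

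The other values singled out are given without an explanation. Cervical loop replicate 2 had 72.6% of its spots well above background against 77.6% to 78.9% on the other arrays of its stage, and 38.6% of its ultraconserved-element probes against 48.1% to 50%. Maturation replicate 5 had a mean correlation of 0.989 with its stage, below 0.992 to 0.993, and lay apart for uc.277+ at -2.55 (others -3.49 to -3.25) and for Cyp2e1 at -6.31 (others -7.35 to -7.09). Maturation replicate 2 had a Ptk2b signal of 0.33, against -0.36 to -0.27. Secretory replicate 1 lay lowest for Cyp2e1 at -6.96 (others -6.21 to -5.96) and for uc.350+ at -7.41 (others -6.49 to -6.35), neither well above background in that stage. Secretory replicate 3 had a uc.398- signal of -0.86 against 0.73 to 1.31.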

How the results depend on the processing

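Normexp correction on the median signal, the scan as a fixed block, lower bounds for stages not measured (bounds under 2-fold for 443, 250 and 101 of the features at 2-fold), the joint omission of cervical loop replicate 3 and maturation replicate 5, and all alternatives for ultraconserved-element probes, a class taken up once the array contents were known, were chosen after seeing the data. Of the values of named genes and probes under alternatives other than leaving out an array, 695 kept direction and call, 8 kept direction and lost the call, and 2 changed sign. Many of these alternatives refit the same normalized values, so that a direction could hardly change, and the named values had been chosen as large differences. The lost calls and changed signs came with normexp correction, quantile normalization, median scaling or the scan as a fixed block. Of the counts, 166 stayed within 1.5 times and 37 did not. Groups of 3 counts are for secretory stage against cervical loop, maturation against secretory stage and maturation against cervical loop, in this order.

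With normexp correction, 2902, 3057 and 2840 features and 17, 17 and 14 ultraconserved-element probes differed at least 2-fold, and 630, 975 and 835 features were highest in cervical loop, secretory stage and maturation. Cyp2e1 changed sign between secretory stage and cervical loop (0.14), and uc.129- between maturation and secretory stage (-0.12). The offset of 50 in this correction is of the size of the arrays' median signals, 30.0 to 76.2, and draws dim probes together. Quantile normalization gave 46 and 84 ultraconserved-element probes for maturation against secretory stage and cervical loop, and 1676 features highest in the cervical loop. Median scaling gave 51 such probes between maturation and secretory stage, 1619 features highest in the cervical loop and 2340 in maturation. The series table gave 42 and 69 probes for the same comparisons, and 1569 features highest in the cervical loop. For these 3 alternatives the cause was not tested.

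Without a filter on dim probes, 962 ultraconserved-element probes were tested in place of 390, and 175, 130 and 287 differed at least 2-fold. With probes well above background on all 15 arrays, 267 were tested and 46, 42 and 71 differed; 5453 features differed at least 2-fold between maturation and cervical loop, and 1356 were highest in the cervical loop. With the scan as a fixed block, 5035 features differed between maturation and secretory stage, 3834 of them and 33 ultraconserved-element probes at least 2-fold; this contrast rests on 1 maturation array and 3 secretory arrays. With stages from the titles, which mix the tissue labels, limma called 0 features between maturation and secretory stage (7184 at an unadjusted p under 0.05), 0 at least 2-fold and 0 ultraconserved-element probes. It called 11598 features and 84 ultraconserved-element probes at least 2-fold between maturation and cervical loop, 14150 among the stages, and 0 highest in secretory stage or maturation.

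Leaving out each array in turn kept all 195 counts within 1.5 times and all 795 named values on their side of the threshold. The named values had been chosen as large differences past the threshold, so their calls were likely to hold. Other features were not followed singly. The features that differed ranged from 15644 to 17055, 15662 to 17719 and 16954 to 18820. Without cervical loop replicate 3 and maturation replicate 5 together they were 16746, 17276 and 17976. With the replicate number as a block, they were 17135, 17559 and 18483, and the block changed no call of a named gene or probe. Deviations of same-numbered arrays correlated at -0.105 to 0.108 for secretory stage and cervical loop and at -0.00243 to 0.249 for maturation and cervical loop, and 2 of 5 numbers matched best with their own in each. Not every value was over 0.1, so the rule did not mark these arrays as pairs. Whether they came from the same rats stays open. Normexp on the mean signal and the set test fry were not run, since the mean signal was not used here and no gene list could be tested.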

Other observations

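The genes of this paragraph, the class of ultraconserved-element probes, its random sets under quantile normalization, normexp correction and the scan as a block, their test with arrays as units, the recount of strands on measured elements, and the reading of the scan and strand tests as undecided were chosen only after results were seen; the other tests were set before their own results were known. Trim2, a ubiquitin ligase gene, rose by 0.52 from cervical loop to secretory stage (adjusted p = 0.025) and by 0.75 from there to maturation (adjusted p = 0.00287). Ndfip2 rose by 1.01 and 0.55 at the same steps. Med16 fell by 1.11 in the secretory stage and rose by 0.94 in maturation. These calls held under 3 scalings between arrays and with normexp correction.

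Ultraconserved-element probes were mostly lower in maturation than in the secretory stage, a call that camera lost at the estimated correlation among them (adjusted p = 0.476). Of 10000 random sets of unnamed probes with the same signal levels, 0% had a median as low as -0.53 (95% of them from -0.36 to -0.17; with normexp correction -0.39 against -0.36 to -0.31), and with arrays as units the difference between class and matched sets changed by -0.28 from secretory stage to maturation (-0.08 with normexp correction; exact permutation p = 0.00794 each, n = 5 arrays per stage), which argues against a fall of all dim probes alike. Quantile normalization, the only scaling run that can move their difference from all features, left it at -0.25 (-0.41 before), with a median of -0.26 against -0.11 to 0.07 in random sets (-0.27 with arrays as units, exact permutation p = 0.00794), which argues against scaling as the whole cause. These permutations of arrays took no account of same-numbered pairs, and 5 pairs are too few for an exact two-sided p under 0.05. In the scan that held both stages, the 3 secretory arrays gave differences of -0.13, -0.22 and -0.12, against -0.41 over all arrays and -0.15 with the scan as a block, where the median was -0.22 against -0.12 to 0.03 in random sets. All lay below 0, the bound set beforehand to exclude a scan effect, but that bound was wrong, since each of these values rests on 1 maturation array and random sets give the spread of probes, not of arrays; stage and scan cannot be told apart here, and no biological reading is drawn.

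Both strands were tested for 104 elements, and the stage differences of opposite strands correlated at a mean r of 0.179 over elements, which are not independent replicates (one-sided permutation p = 0.0105, 0.0167 after adjustment over both tests of this paragraph). A rule set beforehand would have read this as 1 signal reported by both strands. It was set aside after the result was seen, because 7 of the 34 elements with both strands past the threshold between secretory stage and maturation went in opposite directions. Not all of these were measured on every array; in a later recount of the 18 that were, 15 went in the same direction and 3 in opposite ones. Among the 3, uc.46 differed by -0.75 on the plus strand and 0.86 on the minus strand. Most such pairs would share a direction without any link between strands. Of the ultraconserved-element probes past the threshold, 206 were lower and 31 higher in maturation than in the secretory stage. The 174 pairs of consecutively numbered elements correlated at a mean r of 0.135 (one-sided permutation p = 0.0167, the same after adjustment). A prediction written beforehand would have read this as neighbours that share stage differences; the correlations are small, and no explanation is drawn from either.

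Among 100 splits of the arrays into groups of the same sizes, 1 split, the real one, gave a count as large for each result. This argues against chance as the source of the counts. The splits took no account of same-numbered pairs and cannot separate stage from scan. Between secretory stage and cervical loop, 16769 features differed against at most 3034 in another split, 6996 against 1678 at least 2-fold, and 101 against 15 ultraconserved-element probes at least 2-fold. Between maturation and secretory stage the values were 17160 against 7501, 6491 against 2447 and 79 against 34. Between maturation and cervical loop they were 18255 against 7437, 8193 against 3369 and 146 against 80. Among splits of all 15 arrays, 23945 features differed among the stages against 1, and those highest in a stage numbered 2713 against 1 for the cervical loop, 1505 against 0 for the secretory stage and 1344 against 0 for maturation. Of the 16 splits that part every same-numbered pair of secretory and maturation arrays, the real one called 17160 features and the others at most 13. This check covered that count only, and 16 splits are too few for a share under 0.05.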
